A study of Homo sapiens with 26 samples.

How the data were processed

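Gene expression was measured in premalignant lesions of the mouth from 13 patients. The lesion was treated 4 times a day for 6 weeks with a gel whose content of freeze-dried black raspberries was 10%. Each patient gave tissue before the gel (pre) and from the treated lesion afterwards (post), so the 26 arrays form 13 pairs, which are called pairs A to M here. Per the labels' protocols, 25 ng of total RNA was amplified and biotin-labelled as cDNA with a linear isothermal amplification, and each sample was hybridised to its own 1-colour Affymetrix array. The deposited table holds 1 intensity per probe set and array on a linear scale, and GCOS and RMA are named in the submitters' processing notes without versions. Medians of the arrays ran from 27.6 to 31.2 and their means from 150.3 to 178.0, so the deposited intensities had been brought to a similar level by the authors before deposit. The 75th percentiles ran from 77.8 to 110.7, so the distributions of the arrays were not the same. That the deposited intensities are RMA values raised from the log2 scale was inferred from the values and is not stated in the sources used here. No scan date or batch was given in the sources used here, so no batch could be tested, and the number of arrays limits the precision of every value.

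Intensities were transformed as log2(value + 1), and every fold change is on that scale. Of the 22277 probe sets, 19070 carried 1 gene symbol in the platform annotation, 1043 carried several, and 2164 were unnamed there. Entrez identifiers matched the human RefSeq gene table for 19058 of the probe sets with 1 symbol. Probe sets with several symbols or none, the 62 Affymetrix control probe sets, and 31 probe sets of the Y chromosome or XIST were left out. The 19033 remaining probe sets gave 11939 genes, each represented by the probe set with the highest mean over all arrays.

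Post was compared with pre by limma version 3.58.1 (lmFit and eBayes, R 4.3.3) with the pair as a fixed block, which is the comparison of each patient with their own baseline that the study design names. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. The pairing was checked on the data: after subtracting the mean of each group, the arrays of a pair correlated at 0.435 on average against -0.035 between pairs, over 0.1 in 12 of 13 pairs, with the lowest at -0.050. No re-pairing of the post arrays among 100000 reached that mean (one-sided permutation p = 1e-05, the smallest these resamples can give). A check of sex-linked transcripts placed both arrays of a pair in the same class in 13 of 13 pairs.

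Gene lists were fixed before the data were examined. The 25 process lists covered prostanoid and nitric oxide enzymes, cytokines and chemokines, NF-kB feedback genes, immediate early genes, the interferon response, NRF2 antioxidant genes, xenobiotic and AHR genes, cornified envelope genes, non-keratinised oral epithelium, basal keratinocytes, activated keratinocytes, the cell cycle, apoptosis inhibitors, apoptosis promoters, p53 targets, splicing and RNA processing, endosomal sorting and receptor recycling, growth factors and receptors, hypoxia, the unfolded protein response, heat shock, oxidative phosphorylation, cytosolic ribosomal proteins, proteasome subunits, and matrix remodelling and wound repair. Of their 758 genes, 664 were measured. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists, and also with the correlation estimated per list and with fry, which tests whether the genes of a list move one way on balance. Markers of 17 cell types (267 genes, 230 measured, 4 of them also in another list) were tested by the mean change of a list within each pair, with an exact two-sided sign-flip permutation test over the 8192 sign patterns and adjustment over the 17 lists. The inflammatory genes PTGS2, NOS2, VEGFA, TNF, IL1B, IL6, CXCL8, NFKB1, RELA, PTGES and ALOX5 were also adjusted over that list alone. RNA integrity was read from the 3' minus 5' log2 signal of the actin and GAPDH control probe sets, tested by exact sign flips.

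The rule for named genes, also fixed before the data were examined, took the 10 genes per direction with the smallest p among those changed that way in at least 10 of 13 pairs, then the 3 members with the smallest p of each list that passed its test and of 8 lists in any case, then PTGS2, NOS2 and VEGFA. No gene passed the threshold, so the 10 per direction were filled by unadjusted p. Genes named outside that rule are said to have been chosen after their values were seen.

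The gene and list tests were run on simulated data of 11939 genes in 13 pairs before use. Of 100 genes changed by 0.5 on the log2 scale 58 were recovered, and of 100 changed by 1 on that scale 93 were. Among 11739 unchanged genes 11 were called, and no list of 25 was called when independent genes were left unchanged. Genes of the real lists were correlated, at an estimated 0.56 for oxidative phosphorylation. The simulation therefore could not show how often camera with the preset correlation calls unchanged lists of correlated genes. Of 300 sets of 13 random normal values with no change, 9 had a sign-flip p of 0.05 or less. These sets held no gene list.

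Alternatives set beforehand were no replicate block, the pair as a random block, quantile normalization, centring each array on its median, leaving out dim genes, the mean of a gene's probe sets, the probe set with the largest SD, every probe set tested singly, eBayes with trend and robust settings, array weights, covariates for tissue composition, skeletal muscle and the 3' minus 5' signal, a threshold of 0.10, and leaving out each pair in turn. Alternatives added after seeing the data were removal of the trend of change with intensity by cyclic loess between arrays, no offset before log2, leaving out pairs whose arrays differed by over 0.2 in the 75th percentile of log2 values or by over 0.5, 1 or 1.2 in the 3' minus 5' signal, and an exact sign-flip test of list means. Plots were drawn with matplotlib.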

Results

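Expression was profiled in 26 samples of human premalignant oral lesions, 13 taken before and 13 taken after 6 weeks of a topical black raspberry gel, with both samples of a pair from the same patient. The array measured 11939 named genes. The median intensity of an array was 28.4 ± 0.59 (SD, n = 13) before and 29.2 ± 0.89 after treatment. The 75th percentile of the log2 values was 6.66 ± 0.10 before and 6.53 ± 0.14 after, a mean change of -0.13 ± 0.16 (SD over 13 pairs), lower in 9 of 13 pairs (exact sign-flip permutation p = 0.016). The 3' minus 5' signal of the actin and GAPDH control probe sets, a measure of RNA integrity and amplification, was 2.85 ± 0.55 before and 3.11 ± 0.55 after (exact sign-flip permutation p = 0.24, n = 13 pairs). It differed by over 1 between the arrays of a pair in 4 pairs.

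The first comparison asked which genes differed in the lesion after the gel from the baseline of the same patient. No gene passed the threshold, and the smallest adjusted p (limma) was 0.060. Of the 6 genes with an adjusted p under 0.10, 5 were lower after treatment and HUNK was higher. CLK1, a kinase that phosphorylates SR splicing factors, was at a log2 intensity of 8.11 ± 0.46 (SD, n = 13) before and 7.37 ± 0.35 after, a change of -0.73 ± 0.13 (SE), with 12 of 13 pairs lower (limma adjusted p = 0.088). The SR protein SRSF5 was at -0.49 ± 0.10 in 13 of 13 pairs (limma adjusted p = 0.13). However, the probe set of this gene with the largest SD gave a log2 change of 0.033, so the fall was not seen there. The arginine and serine rich proteins RSRP1 and PNISR were at -0.74 ± 0.15 and -0.55 ± 0.11. TMCC1, a membrane protein of the endoplasmic reticulum, was at -0.55 ± 0.08 in 12 of 13 pairs and had the smallest p of all genes. The mitochondrial magnesium channel MRS2 was at -0.72 ± 0.12, the oxysterol-binding protein OSBPL9 at -0.53 ± 0.10 and RMDN1 at -0.56 ± 0.10. The mitochondrial ribosomal protein MRPL48 was at -0.55 ± 0.11 and the lysosomal protease CTSV at -0.64 ± 0.13. These 5 genes were each lower in at least 12 of 13 pairs.

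Of the genes higher after treatment, HUNK, a serine/threonine kinase, stood nearest to the threshold, with log2 intensities of 5.06 before and 5.58 after, a change of 0.52 ± 0.09 (SE) in 13 of 13 pairs (limma adjusted p = 0.088). The others by the naming rule were DLEC1 at 0.40 ± 0.09, TRPM1 (also on the melanocyte list) at 0.47 ± 0.12, the fibrinogen chain FGB at 0.49 ± 0.12, GPRIN2 at 0.46 ± 0.12 and PPP1R17 at 0.35 ± 0.09. NDST4 was at 0.35 ± 0.09, aromatase (CYP19A1) at 0.34 ± 0.08, RIMS1 at 0.33 ± 0.08 and HGC6.3 at 0.32 ± 0.08. Adjusted p ran from 0.177 to 0.188 for these 9 genes. Their mean log2 intensities before treatment ran from 3.33 for NDST4 to 5.95 for GPRIN2. With the trend of change with intensity removed, their changes ran from 0.24 for CYP19A1 to 0.57 for GPRIN2. All but GPRIN2 were then smaller, with DLEC1 at 0.30, NDST4 at 0.26 and PPP1R17 at 0.26. Without pair M, 9 genes passed 0.05 (limma), all lower, and without pair C 1 gene did, TMCC1.

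At an unadjusted p under 0.05, 695 genes were higher and 1220 lower, against 597 in all if p-values were uniform. Other splits of the arrays that part every pair gave a median of 481 in all and up to 3348. The higher count was 451, 453 or 436 without pair B, E or J and 1154 without pair K. Without the 5 pairs of unequal 75th percentile the counts were 144 and 228, together under 597. In all 5 (A, B, E, H and J) the post array had the lower value, so this removal took out shifts in 1 direction. With the pair as a random block in place of a fixed one, 1000 genes were higher and 1038 lower. The direction depended on intensity: the median change was 0.11 in the second decile of genes by mean intensity and -0.17 in the eighth. With this trend removed the counts were 575 higher and 659 lower, and with each array centred on its median 434 and 1558, with no gene past an adjusted p of 0.05 (limma) in either. Without the 4 pairs of unequal 3' minus 5' signal, 454 genes passed the threshold (148 higher and 306 lower, limma, 9 pairs). This removal was chosen after seeing the data, and the count was 3 when the limit was set at 0.5, which leaves out pair E as well, and 884 when it was set at 1.2. For the same 9 pairs it was 83 with the intensity trend removed and 4 with quantile normalization.

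**Figure D1:**
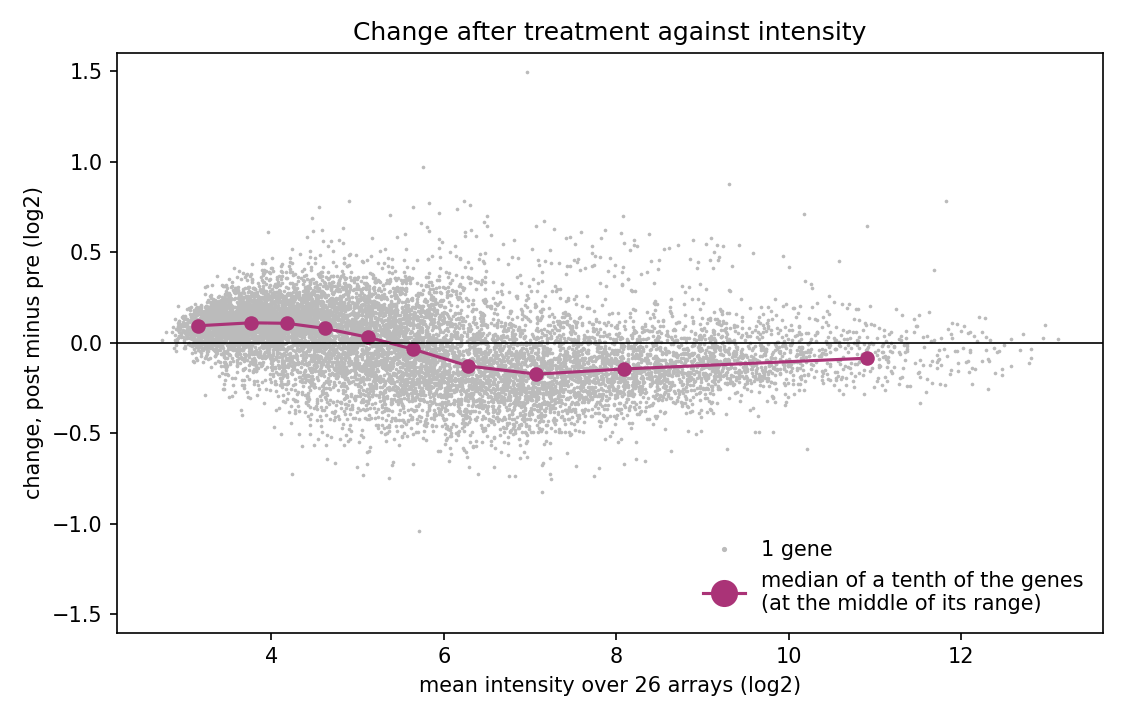
Change after treatment (log2, post minus pre, 13 pairs) against mean log2 intensity over 26 arrays, with 1 point per gene and the median of each decile of genes as larger joined points. The medians lie above 0 for dim genes and fall to -0.17 in the eighth decile.

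The second comparison asked whether genes of known processes differed together. In camera with the preset correlation, 9 of 25 lists passed, 1 higher and 8 lower after treatment, and none passed with the correlation estimated per list, by fry or by sign flips over pairs. At an unadjusted p under 0.05 the counts by these 3 tests were 0, 8 and 8. By camera with the preset correlation, other splits of the arrays that part every pair called a median of 8 lists and up to 16. Matrix remodelling and wound repair genes, which include collagens and their regulators, had a median change of 0.39 (adjusted p = 1.35e-07), and 29 of 32 members were above 0. That call was lost at adjusted p = 0.52 with an estimated correlation. COL3A1, a fibrillar collagen, was at 0.40 ± 0.14 (SE) and higher in 10 of 13 pairs, the matrix glycoprotein TNC was at 0.62 ± 0.23 in 10 of 13, and INHBA, a subunit of activin A, was at 0.39 ± 0.14 in 11 of 13. The mean change of the list was above 0 in 9 of 13 pairs and reached 2.30 in pair E and 1.23 in pair F, with a median over pairs of 0.058 (exact sign-flip permutation p = 0.084, n = 13). Fibroblast markers, which mark the same tissue compartment, were at a mean change of 0.078 ± 0.39 (SD over 13 pairs).

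Genes of oxidative phosphorylation had a median change of -0.21, with 39 of 40 members below 0 (adjusted p = 1.00e-09, and adjusted p = 0.52 with an estimated correlation). NDUFA2 was at -0.48 ± 0.15 (SE), ATP5PF at -0.32 ± 0.10 and NDUFB5 at -0.26 ± 0.09. Cytosolic ribosomal proteins had a median of -0.14 with 33 of 34 members below 0 (adjusted p = 4.57e-06, and adjusted p = 0.52 with an estimated correlation), with RPS21 at -0.33 ± 0.10, RPL35 at -0.37 ± 0.13 and RPL8 at -0.28 ± 0.10. Proteasome subunits had a median of -0.18 with 26 of 27 members below 0 (adjusted p = 4.57e-06, and adjusted p = 0.51 with an estimated correlation), among them PSMD12 at -0.28 ± 0.09, PSMB7 at -0.17 ± 0.07 and PSMD14 at -0.21 ± 0.08. Heat shock genes had a median of -0.19 with 15 of 16 members below 0 (adjusted p = 0.0033, and adjusted p = 0.51 with an estimated correlation), with HSPA1L at -0.40 ± 0.13, BAG3 at -0.29 ± 0.14 and DNAJB6 at -0.17 ± 0.09. Members of a list moved together (estimated correlation 0.56 for oxidative phosphorylation), so counts of members are not counts of independent results. In the order given, the list means were lower in 9, 10, 10 and 11 of 13 pairs. Their exact sign-flip permutation tests gave adjusted p of 0.10, 0.10, 0.081 and 0.081. Above a mean log2 intensity of 6.65, the deciles of all genes had medians from -0.17 to -0.085. The array's 75th percentile was lower after treatment in 9 of 13 pairs.

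Targets of the tumour suppressor p53 had a median change of -0.29, with 9 of 13 members below 0 (adjusted p = 0.0084, and adjusted p = 0.51 with an estimated correlation), and their mean was lower in 11 of 13 pairs. GADD45A, a growth arrest gene induced by DNA damage, was at -0.46 ± 0.09 (SE) and lower in 13 of 13 pairs, TIGAR was at -0.45 ± 0.13 in 11 of 13 and TP53I3 at -0.60 ± 0.19 in 10 of 13. Adjusted over the list alone 3 of its genes passed 0.05, and over all genes 0 did. Apoptosis inhibitors had a median of -0.15, with 19 of 23 members below 0 (adjusted p = 0.0033, and adjusted p = 0.51 with an estimated correlation), including CFLAR at -0.42 ± 0.13, AKT1 at -0.31 ± 0.14 and FAIM at -0.32 ± 0.15. Apoptosis promoters had a median of -0.014 (adjusted p = 0.74).

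Splicing and RNA processing factors had a median change of -0.10, with 51 of 65 members below 0 (adjusted p = 0.00014, and adjusted p = 0.52 with an estimated correlation). Besides CLK1 and SRSF5, SRSF7 was at -0.49 ± 0.12 (SE) and lower in 11 of 13 pairs, and 3 members passed when adjusted over the list alone. Genes of endosomal sorting and receptor recycling had a median of -0.14, with 39 of 48 members below 0 (adjusted p = 0.00088, and adjusted p = 0.52 with an estimated correlation), among them SNX2 at -0.28 ± 0.09, RAB5C at -0.25 ± 0.09 and RAB11B at -0.40 ± 0.15. With the trend of change with intensity removed, the splicing median turned to 0.0077 while its mean went from -0.12 to -0.041 and its test still pointed down (adjusted p = 0.29). The endosomal, proteasome and apoptosis inhibitor lists then missed the threshold too, at adjusted p of 0.067, 0.072 and 0.12, while the other 5 lists passed it. The basal keratinocyte, growth factor, immediate early and interferon lists then passed, all higher, at adjusted p of 0.0059, 0.021, 0.017 and 0.019. With an estimated correlation on that scale these were adjusted p = 0.47, 0.47, 0.57 and 0.82, and by sign flips no list passed.

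**Figure D2:**
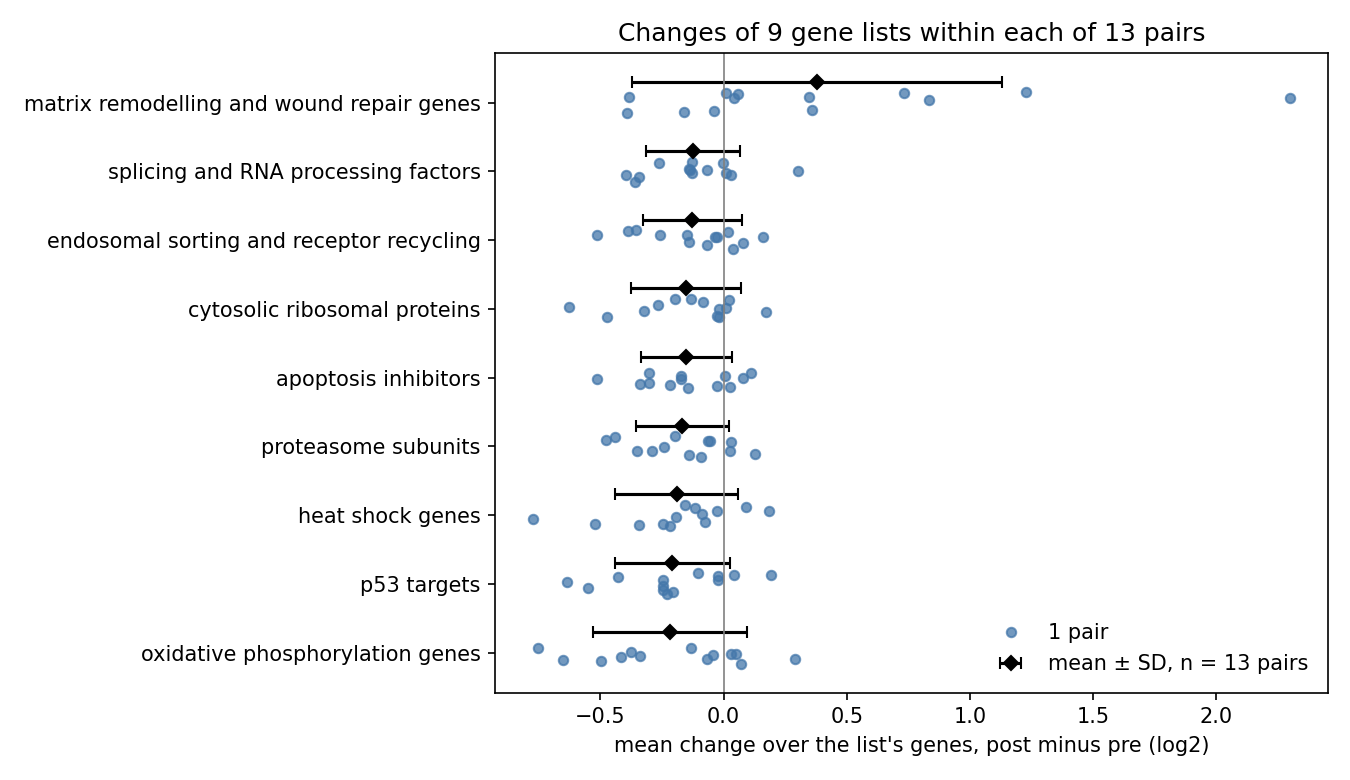
Mean log2 change (post minus pre) over the genes of the 9 lists that passed camera with the preset correlation, with 1 blue point per pair and the mean ± SD over 13 pairs as a black diamond. The matrix remodelling list spreads from -0.39 to 2.30, and the p53 target list is below 0 in 11 of 13 pairs.

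The remaining 16 lists did not pass. Cytokines and chemokines had a median change of 0.18 (adjusted p = 0.082), with 23 of 30 members above 0. IL18, an epithelial cytokine, was at -0.83 ± 0.18 (SE) and lower in 11 of 13 pairs, while the chemokine CCL20 was at 0.78 ± 0.31 and TGFB1 at 0.30 ± 0.14. IL18 was the only member to pass when adjusted over the list alone. Epithelial lists gave medians of 0.075 for basal keratinocyte genes, -0.15 for activated keratinocyte genes, -0.17 for non-keratinised oral epithelium and -0.038 for cornified envelope genes. In the last of these SCEL was at -0.50 ± 0.16, SPRR3 at 0.78 ± 0.46 and TGM1 at -0.29 ± 0.20. NRF2 antioxidant genes had a median of -0.089, with the haem oxygenase HMOX1 at -0.38 ± 0.14, ME1 at -0.35 ± 0.16 and GCLM at -0.19 ± 0.09. Cell cycle genes had a median of -0.0051, with CCNE2 at -0.33 ± 0.11, CCNE1 at -0.42 ± 0.18 and BUB1 at 0.25 ± 0.11. The medians were 0.16 for the interferon response, 0.086 for NF-kB feedback genes, 0.053 for immediate early genes, 0.039 for growth factors and receptors, -0.062 for xenobiotic and AHR genes, -0.075 for hypoxia genes and -0.070 for the unfolded protein response.

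The series title names proinflammatory proteins, and the third comparison took the genes of that kind. PTGS2, which encodes the inducible cyclooxygenase COX-2, was at a log2 intensity of 5.997 ± 0.82 (SD, n = 13) before and 6.62 ± 1.54 after. Its change of 0.62 ± 0.39 (SE, limma adjusted p = 0.41) had a 95% confidence interval from -0.20 to 1.44, and 9 of 13 pairs were higher. Pair E went from 5.01 to 9.98, and without it the mean change of PTGS2 was 0.26. NOS2, the inducible nitric oxide synthase, was at 4.23 ± 0.21 before and 4.33 ± 0.27 after (0.10 ± 0.11, limma adjusted p = 0.63). VEGFA was at -0.37 ± 0.18 (limma adjusted p = 0.32) and lower in 9 of 13 pairs, but its 4 probe sets disagreed, at -0.37, -0.31, -0.025 and 0.12. None of the 11 genes of this list passed when adjusted over the list alone or over all genes, and the smallest adjusted p over the list alone was 0.36. No gene of the list had an unadjusted p under 0.05 at its chosen probe set, while the VEGFA probe set at -0.31 had an unadjusted p of 0.0016. CXCL8 was at 0.78 ± 0.49, IL6 at 0.39 ± 0.32, IL1B at 0.17 ± 0.30, TNF at 0.11 ± 0.13, PTGES at 0.0024 ± 0.23 and NFKB1 at -0.15 ± 0.12. ALOX5 was at -0.16 ± 0.18 and RELA at -0.27 ± 0.15. Without pair E the mean changes were 0.28 for CXCL8, 0.037 for IL6, -0.11 for IL1B, -0.0019 for TNF and -0.12 for PTGES. Leaving out each pair in turn, the mean changes ran from 0.058 to 0.16 for NOS2, -0.47 to -0.28 for VEGFA, 0.26 to 0.78 for PTGS2, 0.28 to 1.005 for CXCL8, 0.037 to 0.50 for IL6 and -0.11 to 0.33 for IL1B. They ran from -0.0019 to 0.17 for TNF, -0.12 to 0.12 for PTGES, -0.24 to -0.11 for NFKB1, -0.30 to -0.053 for ALOX5 and -0.37 to -0.18 for RELA. The list of prostanoid and nitric oxide enzymes had a median of -0.0012 and a mean of -0.025, while its camera test pointed up (adjusted p = 0.99). HPGD, which degrades prostaglandins, was at -0.60 ± 0.24, PTGES2 at 0.25 ± 0.12 and PLA2G4A at -0.25 ± 0.13.

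**Figure D3:**
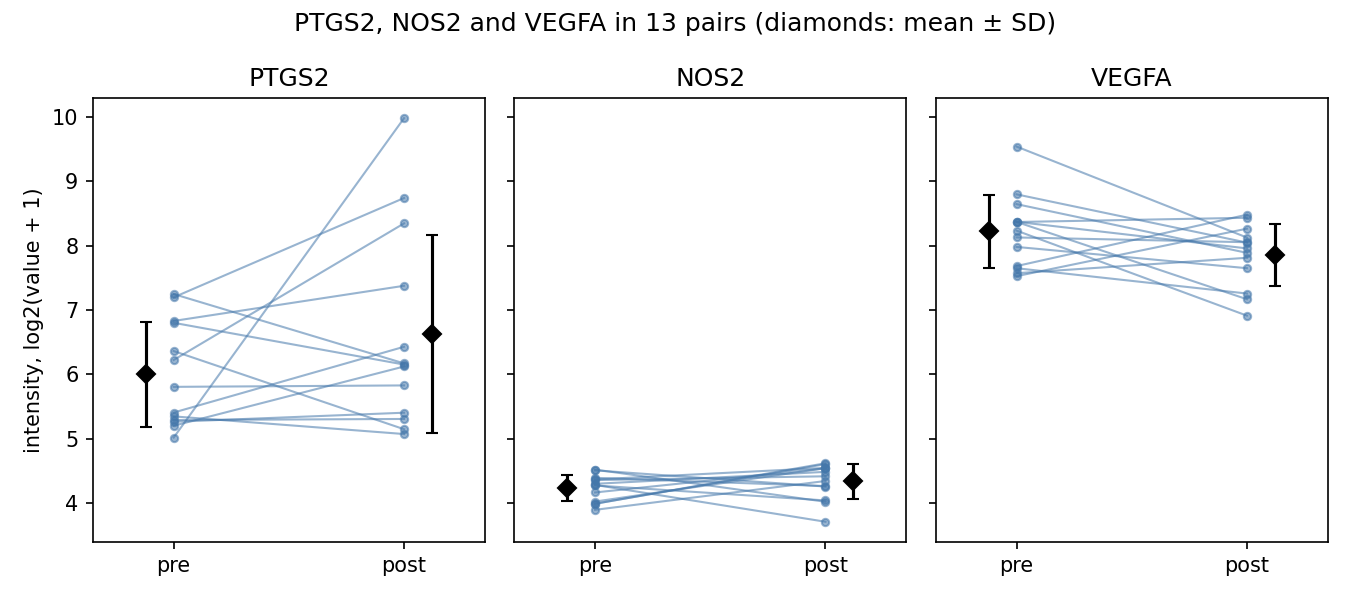
Log2 intensity of PTGS2, NOS2 and VEGFA before and after treatment, with a line per pair and the mean ± SD (n = 13) as a black diamond. PTGS2 spread more after treatment (SD 1.54) than before (SD 0.82).

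The fourth comparison asked whether the cells held by the tissue pieces differed. None of the 17 marker lists passed the exact sign-flip permutation test after adjustment over the 17 lists, and none had an unadjusted p under 0.05. Camera with the preset correlation also called none, with the smallest adjusted p at 0.061. With the intensity trend removed, which was chosen after seeing the data, camera called endothelial (adjusted p = 0.013) and fibroblast markers (adjusted p = 0.035), both higher. The sign-flip test over pairs on that scale gave adjusted p of 0.42 and 0.83 for them. On the deposited scale, the lists with the smallest sign-flip p were B cell markers at a mean change of 0.13 ± 0.22 (SD over 13 pairs, unadjusted p = 0.062) and endothelial markers at 0.13 ± 0.26 in 10 of 13 pairs (unadjusted p = 0.078), both at an adjusted p of 0.66. B cell markers were dim, at a mean level of 3.80 before treatment. With the intensity trend removed their mean change was 0.041 (unadjusted sign-flip p = 0.24), and that of endothelial markers was 0.17 (unadjusted sign-flip p = 0.024). Skeletal muscle markers had the widest spread, 0.19 ± 1.80, from -2.63 in pair L to 4.56 in pair H. Mean changes were 0.14 for NK cell, 0.12 for melanocyte, 0.11 for red blood cell, 0.10 for Schwann cell, 0.095 for salivary gland, 0.089 for neutrophil and 0.082 for pericyte and smooth muscle markers. They were 0.076 for T cell, 0.054 for mast cell, 0.050 for dendritic and Langerhans cell, 0.013 for macrophage, -0.013 for plasma cell and -0.024 for adipocyte markers. Among abundant markers, DCN of fibroblasts was at 10.24 before and 10.25 after, LUM at 10.50 and 10.72, PECAM1 of endothelium at 9.70 and 9.82, and LYZ of macrophages at 10.41 and 10.63.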

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

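Alternatives with the intensity trend removed, without an offset, without pairs of unequal 75th percentile or 3' minus 5' signal, and by sign flips of list means were chosen after seeing the data. Counts of genes past an adjusted p of 0.05 (limma) were 0 with all 13 pairs, 10 with array weights, 2 with the composition covariate, and 6 at a threshold of 0.10. Leaving out 1 pair gave 0 to 9 genes, with 9 without pair M and 1 without pair C. Without the 4 pairs of unequal 3' minus 5' signal (D, G, K and M) the count was 454, and for the same 9 pairs it was 83 with the intensity trend removed and 4 with quantile normalization. It was 3 without pairs over 0.5 and 884 without pairs over 1.2 (K and M). The other alternatives gave 0. The cause was not tested for array weights or the covariate.

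Genes higher at an unadjusted p under 0.05 numbered 434 with medians centred, 175 with dim genes left out (7013 genes tested), 1270 with array weights, 144 without the 5 pairs of unequal 75th percentile, 1639 without the 4 pairs, 1194 with every probe set (19033 tested), and 436 to 1154 leaving out each pair, against 695. They were 451, 453 and 436 without pairs B, E and J, and 1154 without pair K. Genes lower numbered 622 without the replicate block (601 higher, 0 past the adjusted threshold), 704 with quantile normalization, 659 with the trend removed, 228 without the 5 pairs, 2156 without the 4 pairs, 1879 with every probe set, and 863 to 1629 leaving out each pair, against 1220.

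The count of 9 lists ran from 9 to 13 when each pair was left out, with all 9 kept each time; the block changed no list's call. It was 0 with the correlation estimated per list, 0 by fry, and 0 by the exact sign-flip test with or without the trend. With the trend removed, or with quantile normalization, 5 and 7 of the 9 stayed and 4 others passed (basal keratinocyte, growth factor, immediate early and interferon genes). With dim genes left out 5 of the 9 stayed, without apoptosis inhibitors, endosomal sorting, heat shock and splicing. The 4 others that passed with the trend removed then passed too, and so did cytokines and chemokines. The cytokine list also passed with medians centred and without pair C, F, I or J. Without the 5 pairs of unequal 75th percentile, all lower in the post array, 4 of the 9 stayed. Apoptosis inhibitors, endosomal sorting, heat shock, splicing and ribosomal proteins were lost. In that setting, with 8 pairs left, endosomal sorting turned to 0.023, and NRF2 antioxidant genes (0.15) and cornified envelope genes (0.19) passed in the direction opposite to their medians over 13 pairs. The count of cell type lists stayed at 0 in the alternatives run on its sign-flip test and by camera on the deposited scale. Among probe sets of PTGS2, NOS2 and VEGFA tested singly, 1 passed over those alone (VEGFA at -0.31). The similarity within pairs ranged from 0.408 to 0.478 leaving out each pair. All 63 named genes kept their sign when any 1 pair was left out, which their choice from the same 13 pairs made likely. With the probe set of the largest SD 62 kept it, and without the 5 pairs of unequal 75th percentile 60 did. Signal over background was not measured, so what dim genes can show is open.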

Other observations

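Single pairs showed large differences shared by many genes that averages over 13 pairs hide. The tests in this part were chosen after the results they measure were seen, except the test of all genes over 13 pairs, camera on the deposited scale with the preset or an estimated correlation, and the fits over 13 pairs with the 3' minus 5' covariate, with dim genes left out, with the pair as a random block and without a block. In pair B, interferon response genes were higher by 2.14 on the log2 scale after treatment, with T cell markers at 1.30, cytokines at 1.12 and skeletal muscle markers at -1.64. In pair E, cytokines and chemokines were higher by 2.34, matrix remodelling genes by 2.30 and neutrophil markers by 1.40, and PTGS2 went from 5.01 to 9.98. In the same pair skeletal muscle markers were at 2.70, macrophage markers at 1.15 and endothelial markers at 0.81. Over the 13 pairs the mean changes of these lists were 0.14 ± 0.72 (SD) for the interferon response and 0.20 ± 0.76 for cytokines and chemokines. Non-keratinised oral epithelium genes went from -1.41 in pair M to 1.96 in pair L, where skeletal muscle markers were at -2.63, with 7 of 13 pairs higher. Cornified envelope genes went from -1.21 in pair E to 1.41 in pair M. KRT76, a keratin of masticatory oral epithelium, had the highest mean change of all genes and was chosen after its values were seen. It was at 1.49 ± 0.50 (SE) and higher in 12 of 13 pairs, without passing the threshold (limma adjusted p = 0.24). KRT76 was placed on the non-keratinised oral epithelium list, so that list does not mark non-keratinised epithelium alone.

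Within the 9 pairs whose 3' minus 5' signal differed by 1 or less, the 454 genes past the threshold included 6 of 65 splicing factors, all lower, with CLK1 at -0.90 ± 0.15 (SE) in 9 of 9 pairs (limma adjusted p = 0.032). IL18 was at -1.05 ± 0.18 and lower in 9 of 9, and CCL20, an epithelial chemokine, was at 1.13 ± 0.28 and higher in 9 of 9. The growth factor NRG1 was at 0.60 ± 0.09 and the receptor FGFR1 at 0.88 ± 0.18, each higher in 9 of 9 pairs. GOLGA8A, a golgin family gene with near-identical copies, had the smallest adjusted p, at -1.23 ± 0.12 (limma adjusted p = 0.0024). None of the 454 passed over all 13 pairs. With the intensity trend removed, 1 of the 6 splicing factors still passed (CLK1, limma adjusted p = 0.047). IL18, NRG1, FGFR1 and GOLGA8A kept their calls (limma adjusted p of 0.049, 0.027, 0.047 and 0.0026), while CCL20 at 1.06 ± 0.28 missed the threshold (limma adjusted p = 0.073). With the limit at 0.5, of these 6 genes (CLK1 included) GOLGA8A alone passed (limma adjusted p = 0.0075) and the others lay between 0.059 and 0.076. Their changes were then -0.88 for CLK1, -0.95 for IL18, 0.86 for CCL20, 0.57 for NRG1 and 0.84 for FGFR1. With the limit at 1.2, all but CCL20 passed (limma adjusted p of 0.018 or 0.019). CCL20 was then at 1.04 ± 0.31 (limma adjusted p = 0.051). With quantile normalization of the 9 pairs NRG1 alone passed (limma adjusted p = 0.038), and the change of GOLGA8A was -0.39 ± 0.15 (limma adjusted p = 0.17). The other 4 lay between 0.053 and 0.072, with changes of -0.70 for CLK1, -0.89 for IL18, 1.13 for CCL20 and 1.03 for FGFR1.

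The first pattern is that matrix remodelling and wound repair genes were higher by camera with the preset correlation, a call lost at adjusted p = 0.52 with an estimated correlation and at an exact sign-flip permutation p of 0.084, with a median over pairs of 0.058 and the highest means in pairs E (2.30) and F (1.23). Removal of the intensity trend left their median at 0.46 against 0.39, which argues against that trend as the source. More stromal tissue in the later piece stays open: the matrix list exceeded fibroblast markers by 0.30 ± 0.67 (SD), in 9 of 13 pairs, with an exact sign-flip permutation p of 0.10, and with the intensity trend removed fibroblast markers were higher by camera (adjusted p = 0.035) but not by sign flips (adjusted p = 0.83). Repair after the first biopsy cannot be told apart from the gel, since 0 groups were biopsied at both times without it. For the lists as a whole, 43 of 100 splits of the arrays that part all 13 pairs (the real one included) called 9 or more lists, up to 16. The median of the other splits was 8 lists, so a count of 9 was ordinary among them and chance stays open.

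The second pattern is that more genes were lower than higher at an unadjusted p under 0.05, a share that was 85.7% with dim genes left out but 50.9% with the pair as a random block or without a block. With the intensity trend removed the share was 53.4% against 63.7%. That removal centres the change at each intensity, which by itself moves the share toward balance. The fall therefore cannot decide what caused the excess. The 3' minus 5' signal as a covariate left it at 61.8%, and leaving out the 4 pairs of unequal signal gave 56.8%, which does not decide whether RNA integrity contributes; the bound for this test was raised after both values were seen, and under the first bound RNA integrity would have been excluded. Of 100 splits that part all 13 pairs, 3 (the real one included) had as many genes at an unadjusted p under 0.05. The real split had 1915 and the highest others 3348 and 2017. Such a count was rare among these splits, but chance is not excluded for it. For genes past the adjusted threshold the real count was 0, so 100 of 100 splits reached it, and the highest other split had 827, which may point to a structure of the samples, although the next highest had 2, the median was 0 and no test addressed such a structure.

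The third pattern is the 454 genes past the threshold in 9 pairs. Of 100 removals of 4 pairs, 4 gave as many genes, this one included. All 4 hold pairs K and M, but the other 4 removals that hold both gave 0, 0, 1 and 242 genes, and a limit of 0.5, which adds pair E alone to those left out, gave 3, so whether RNA integrity differences hid changes stays undecided. With the intensity trend removed 76 of the 454 still passed. The median absolute change of the 454 went from 0.59 to 0.49 and their median SE from 0.13 to 0.12. The trend may thus account for some of the calls. With it removed 112 of the changes were larger and 342 smaller, which does not decide how many calls it accounts for. Among 100 splits that part the 9 pairs, 2 gave as many genes, the real one with 454 and another with 639. Such a count was rare for this set of pairs taken alone, but chance is not excluded. Nor is it for the choice of that set, which was made after seeing the data.

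Splits of the arrays without regard to pairs parted 3 to 13 pairs, against 13 in the real split. Of these 100, 6 (the real one included) gave as many genes at an unadjusted p under 0.05, up to 2434. Among splits that part every pair it was 3 of 100. These shares are too close for 100 draws of each kind, and rest on unlike numbers of parted pairs, to rank how rare the count was.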
